A study of Mus musculus with 8 samples.

How the data were processed

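Primary CD4+ T cells of BALB/c mice were profiled in 4 groups of 2 arrays, 8 in all. RNA was isolated with a column kit and labelled with biotin by in vitro transcription, per the labels' protocols. The authors deposited linear intensity values, 1 per probe set and array, for 45101 probe sets. Per the submitters' processing notes, RMA and the affy package were used, with versions not given in the sources used here. The deposited values do not have the form of RMA output, which is on a log2 scale: on every array the mean signal after trimming 2% at each end was 500, and values went down to 0.0605. The arrays had thus been brought to a common level, and between 363 and 884 values per array were under 1. The step that made them is not given in the sources used here. No detection calls were used, so the background of each array is unknown.

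The log2 of the deposited intensity values was taken, with no further normalization. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those said below to have been added later. Genes were named through the platform annotation supplied with the series, updated by Entrez identifier to current symbols. Of the probe sets, 34945 had 1 symbol, 932 several and 9160 none in that table, and 64 were control probe sets. Current symbols were found for 34741, and 0 changed. Each of 18193 genes was represented by its probe set with the highest mean over the 8 arrays. Genes were tested where that probe set exceeded the 40th percentile of all values (log2 5.22, signal 37.3) on at least 2 arrays, which left 13983. Different probe sets of a gene can disagree, and the mean of all of them was an alternative. The same percentile served as a working floor. Where both arrays of a group lay under it, the change is a bound: the brighter group's mean against the mean, per array, of the higher of the floor and the gene's own value.

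All 8 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, no trend, not robust), with 4 residual and 1.90 prior degrees of freedom. The 5 contrasts were stimulation without and with dorsomorphin, dorsomorphin in unstimulated and in stimulated cells, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A log2 fold is the second group's mean minus the first's, and its SE is limma's moderated one. The 30 lists were tested per contrast with camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move 1 way on balance and does not compare them with other genes. Some genes were in 2 lists, among them Il2ra, Tnfrsf4, Tnfrsf18, Ctla4, Foxp3 and Ikzf2, so the calls of such lists are not separate. Overlaps of calls were set beside the number shared by independent lists.

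Named genes followed a fixed rule. Per contrast it took the 12 rising and 12 falling genes with the largest log2 fold among those past the threshold and with no overlap between the arrays of the groups. It added up to 4 members past the threshold per list and a set of fixed genes, Id1, Id2, Id3, Smad6, Smad7, Runx1, Il2, Ifng, Foxp3, Egr1 and Myc. Smad6 lay below the floor and was not tested, and another fixed gene is not reported here. Where fewer than 10 genes passed, the 5 smallest p-values were taken. Symbols that name clones were left out, and 1 of the 12 interaction genes is such a symbol.

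The labels number the replicates 1 and 2 in every group without saying what a number marks. Of 4 poly-A spike-in RNAs, bacterial transcripts added before labelling, Dap and Thr split by the number in all 4 groups: the 3' minus 5' log2 signal of Dap was 1.11 to 1.37 in replicates 1 and 2.44 to 2.79 in replicates 2, and that of Thr 1.62 to 1.76 and 2.69 to 3.29. The ranges of Lys nearly met (1.31 to 1.758 and 1.758 to 2.21), and those of Phe overlapped (0.75 to 0.92 and 0.83 to 1.07). Each number holds 1 array of every group, too few for a test within a number, so the number was used as a block in an alternative fit. Mouse Gapdh and actin control probe sets had 3' minus 5' log2 signals of -0.59 to -0.18 and 0.33 to 0.80 over the 8 arrays. The actin values were lowest on the stimulated arrays without dorsomorphin, at 0.33 on both against 0.47 to 0.80 on the others. Those of Gapdh did not set these arrays apart (-0.49 and -0.32).

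The limma step was tested on data simulated from the 13983 genes' means and spreads. The effects tried first, 200 genes changed by 2- or 4-fold, gave a recovery of 0% of either size in each of the 5 contrasts. Changes of 16- and 64-fold were then added to the mix, after that result was seen, and they ease the adjusted threshold for the smaller ones. With this mix of 200 genes in the stimulation contrast without dorsomorphin, limma recovered 0.70% of 2-fold, 38.4% of 4-fold, 80.6% of 16-fold and 91.9% of 64-fold changes. With 3000 genes changed in that contrast it recovered 18.5% of 2-fold and 71.9% of 4-fold changes, with 4.05% of calls false. In the interaction, 3000 changed genes gave 1.11% and 22.3%. A simulated list shifted by 1 log2 unit was called in 20 of 20 draws with the preset correlation and in 15 with the estimated one. The simulated genes were independent, so this does not test whether the preset correlation holds in the real lists. In ribosome biogenesis, for example, the estimated correlation was 0.46.

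The alternatives were the replicate number as a block, only the 4 arrays of a comparison, no filter or a 60th percentile filter on dim genes, median centring, cyclic loess, a variance trend with a robust fit, the mean of a gene's probe sets, probe sets ending in _x_at left out, stricter thresholds, and each array left out in turn. Quantile normalization and log2 of the value plus 32 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.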

Results

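Messenger RNA levels were measured in primary CD4+ T cells of BALB/c mice on 8 Affymetrix mouse expression arrays, each with 45101 probe sets. The cells were cultured for 1 h with or without antibodies against CD3 and CD28, which together trigger the T cell receptor and a costimulatory receptor. Dorsomorphin at 4 µM or its solvent DMSO was then present for 6 h. Dorsomorphin is a small molecule that inhibits type I receptors for bone morphogenetic proteins (BMPs) and also inhibits the energy-sensing kinase AMPK. The 4 groups were control cells, cells with dorsomorphin, stimulated cells, and stimulated cells with dorsomorphin, with 2 arrays each. The labels do not say whether the replicates came from separate mice or cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value below. Median signals per array ranged from 45.4 to 74.5.

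Arrays of the same group correlated at 0.937 to 0.952 across 13983 genes (Pearson's r of log2 signals, genes not being independent replicates). The 2 stimulated arrays stood apart from the other 6 on the first principal component, which held 38.0% of the variance, at -86.7 and -119. The second component held 26.5% and placed both control arrays, at 87.3 and 87.1, apart from the other 6. The array of stimulated cells with dorsomorphin, replicate 1, correlated at 0.955 with dorsomorphin replicate 1, above its correlation of 0.937 with its own replicate. Replicate 2 of that group also correlated more with dorsomorphin replicate 2 (0.941) than with its own replicate.

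The first comparison asked how CD4+ T cells respond to stimulation in the absence of the inhibitor. Of the measured list members, 14 of 17 T cell cytokines, 7 of 12 chemokines and 13 of 24 activation-induced transcription factors rose, and 14 of 20 quiescence and homing genes fell. Il2, which encodes the T cell growth factor interleukin-2, rose 219-fold (log2 fold 7.78 ± 1.05, SE, n = 2 per group, adjusted p = 0.0113). Ifng, which encodes interferon gamma, rose 70.5-fold (6.14 ± 0.52, adjusted p = 0.00784). Egr2, a transcription factor induced by T cell receptor signals, rose 73.6-fold (6.20 ± 0.30, adjusted p = 0.00497). Pik3ip1, an inhibitor of PI3-kinase, fell by 4.96 ± 0.93 on the log2 scale, and S1pr1, the receptor that guides lymphocyte exit from lymph nodes, fell by 4.38 ± 1.11.

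In all, 1256 genes rose and 2013 fell of 13983 tested by limma. Some large changes had a dim side under the working floor of log2 5.22, and these are given as bounds. Bcat1, a branched-chain amino acid transaminase, rose at least 107-fold, the chemokine gene Ccl1 at least 148-fold and the retinoic acid binding protein gene Crabp2 at least 37.5-fold. Egr3 rose by 6.97 and Hivep3 by 6.30 log2 units. Among the largest falls measured on both sides were Rflnb (-5.14), Mturn (-5.04), the phosphodiesterase gene Pde5a (-4.99) and the sialyltransferase gene St8sia6 (-4.86).

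Of 30 measured ribosome biogenesis genes, 28 rose, 0 fell and 2 did not pass, and 30 rose when adjusted over the list alone. Rrp12 rose by 4.60, Nolc1 by 3.64, the RNA polymerase I subunit gene Polr1b by 3.45 and Nop16 by 3.27 log2 units. The list's camera test gave an adjusted p of 8.92e-23, and adjusted p = 0.188 with an estimated correlation. Of 17 T cell cytokines, 14 rose and 3 did not pass, with 15 adjusted over the list alone, a median of 4.24 and a camera adjusted p of 1.75e-10. Its adjusted p was 0.176 with an estimated correlation. Activation-induced transcription factors had 13 of 24 members up, among them Irf4 at 6.11 and Nr4a3 at 4.61, and 14 adjusted over the list alone. Their camera adjusted p was 8.88e-10, and adjusted p = 0.176 with an estimated correlation. Chemokines had 7 of 12 members up and 5 not passed, with 8 adjusted over the list alone, and Xcl1 rose by 5.61 log2 units (camera adjusted p = 1.68e-05, and adjusted p = 0.176 with an estimated correlation). Among surface molecules, 12 of 21 rose, and 13 adjusted over the list alone. They included the interleukin-2 receptor gene Il2ra at 4.86 and Tnfrsf9 at 3.62, with a camera adjusted p of 7.06e-10 and adjusted p = 0.176 with an estimated correlation.

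Of 22 genes of the ATF4 and amino acid response, 10 rose and 2 fell, with 11 and 2 adjusted over the list alone. The amino acid transporter gene Slc7a5 rose by 3.88, and Psat1 and Asns, which make serine and asparagine, rose by 3.64 and 3.61 log2 units. The camera adjusted p was 6.85e-06, and adjusted p = 0.326 with an estimated correlation. Cholesterol and fatty acid synthesis had 8 of 23 members up, also 8 adjusted over the list alone, including Cyp51 at 3.03 and Fasn at 2.25. Its camera adjusted p was 5.42e-05, and adjusted p = 0.441 with an estimated correlation. Quiescence and homing genes had 14 of 20 members down, and 15 adjusted over the list alone, among them the interleukin-7 receptor gene Il7r at -4.52 and the glucocorticoid-induced gene Tsc22d3 at -4.12. Their camera adjusted p was 5.42e-05, and adjusted p = 0.441 with an estimated correlation. Of 14 BMP and activin ligands, receptors and SMADs, 4 fell, and 4 adjusted over the list alone, including Smad4 at -1.86 and Smad1 at -0.95. Their camera adjusted p was 0.0133, and adjusted p = 0.394 with an estimated correlation. The list BMP and activin ligands, receptors and SMADs was not called with median centring (adjusted p = 0.0504), where its median moved from -0.75 to -0.40, or with the mean of a gene's probe sets (adjusted p = 0.337). Of 16 AMPK subunit and fatty acid oxidation genes, 8 fell, and 10 adjusted over the list alone (camera adjusted p = 0.00744, and adjusted p = 0.394 with an estimated correlation). Myeloid and dendritic cell markers, a sign of other cells in the preparation, had 4 of 20 members down, also 4 adjusted over the list alone. They included the lysozyme gene Lyz2 at -2.48 (camera adjusted p = 0.00436, and adjusted p = 0.441 with an estimated correlation). Without stimulated replicate 2 the adjusted p of Myeloid and dendritic cell markers was 0.0540.

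Camera called 20 of the 30 lists for this comparison, 16 up and 4 down, and 0 of them with an estimated correlation. The median log2 fold of all genes was -0.27, and it was 0.10 after median centring and 0.00 after cyclic loess. These scalings changed the split to 1018 higher and 1045 lower, and to 1600 higher and 1593 lower. Leaving out either control array left 0 genes past the limma threshold, with 3794 and 3813 at an unadjusted p under 0.05, and leaving out stimulated replicate 2 left 680.

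**Figure D1:**
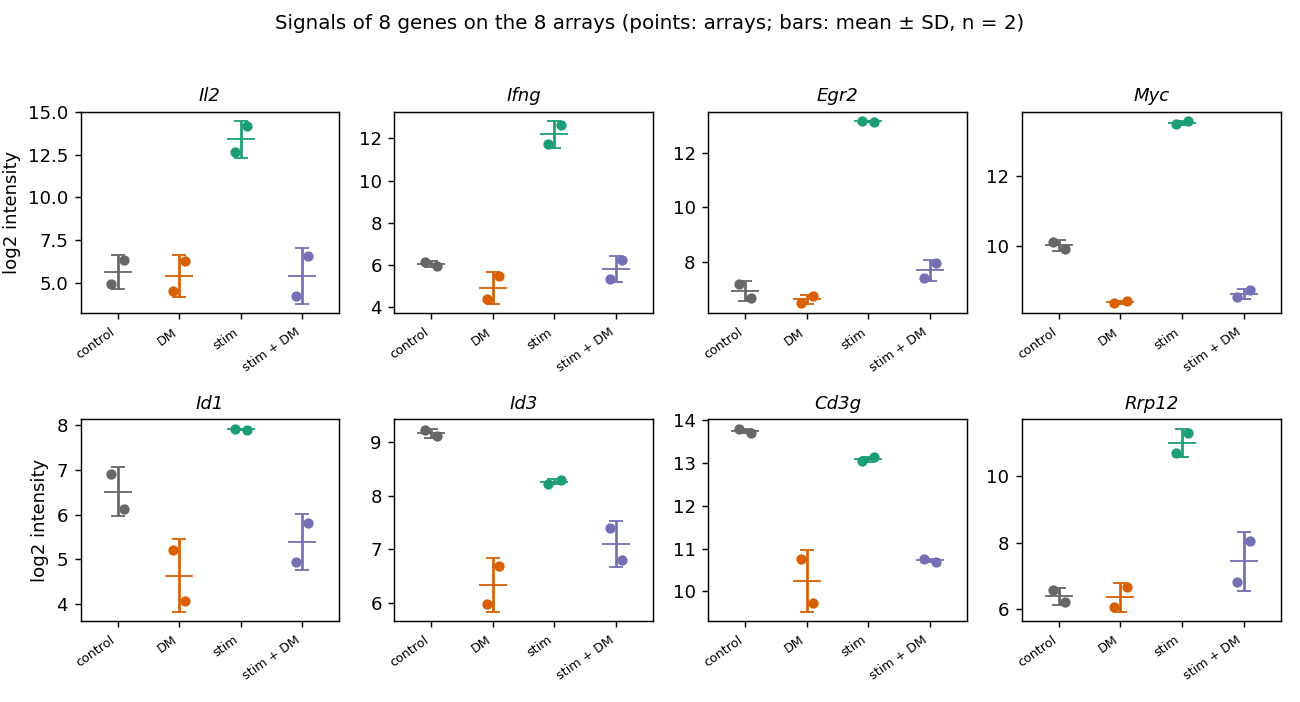
Log2 intensity (vertical axis) of 8 genes in control cells, cells with dorsomorphin (DM), stimulated cells (stim) and stimulated cells with dorsomorphin (stim + DM). Points are single arrays, and bars give the mean ± SD (n = 2), which for Il2 was 13.41 ± 1.08 in stimulated cells and 5.39 ± 1.64 in stimulated cells with dorsomorphin.

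The second comparison asked what dorsomorphin does to unstimulated T cells. Cd3g, a chain of the CD3 complex of the T cell receptor, fell by 3.51 ± 0.35 log2 units (SE, n = 2 per group, adjusted p = 0.0109), and Cd3e, another chain of that complex, fell by 2.22 ± 0.46. The BMP target gene Id3, an inhibitor of DNA-binding E proteins, fell by 2.82 ± 0.33 (adjusted p = 0.0121). Itgae, the CD103 integrin gene, fell by 2.97 ± 0.32, and Rcan1, a calcineurin regulator induced by NFAT, fell by 3.14 ± 0.26. Myc, a growth-promoting transcription factor, fell by 1.62 ± 0.21 (adjusted p = 0.0139). The ubiquitin-editing NF-kappaB inhibitor gene Tnfaip3 rose by 1.66 ± 0.36, and the E3 ligase gene Rnf157 rose by 3.63 ± 0.48.

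In all, 268 genes rose and 1557 fell of 13983. Of the 12 largest rises, Rnf157 was the one with control arrays above the floor, and the highest bound among the others was at least 1.89-fold, for Reg3b. Both means lay above the floor for 216 of the rises and 1333 of the falls. Among the largest falls measured on both sides were the carnosine synthase gene Carns1 (-5.30), Dapl1 (-5.20) and the kinase gene Ikbke (-4.89). Ifi204 fell at least 5.59-fold, and the glycosyltransferase gene Galnt9 at least 8.21-fold.

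Of 17 CD4 T cell identity genes, 0 rose, 7 fell and 10 did not pass, and 12 fell when adjusted over the list alone. Thy1 fell by 2.12 and Cd5, a negative regulator of receptor signalling, by 2.09 log2 units. The list's median was -1.11, or -0.87 relative to all genes (camera adjusted p = 0.000232, and adjusted p = 0.991 with an estimated correlation). Of 11 regulatory T cell markers, 4 fell, and 7 adjusted over the list alone, among them the actin-capping gene Capg at -2.40 and Tnfrsf18 at -1.44. Their camera adjusted p was 0.0161, and adjusted p = 0.991 with an estimated correlation. Regulatory T cell markers were not called without control replicate 1 (adjusted p = 0.0628), without dorsomorphin replicate 1 (0.0774) or with the 60th percentile filter (0.0704). Foxp3, the lineage factor of these cells, had a log2 fold of -1.71 ± 0.43 that did not pass (adjusted p = 0.0523). Beside these T cell groups, myeloid and dendritic cell markers had 4 of 20 members down, and 13 adjusted over the list alone. Adgre1, a macrophage surface receptor gene, fell by 1.40, with a list median of -1.30, a camera adjusted p of 0.00153 and adjusted p = 0.991 with an estimated correlation. The fall of these markers with stimulation was measured against the same control arrays, so the 2 falls are not separate. Of 11 B cell markers 1 fell, and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.420).

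The BMP-SMAD target list, which bears on the inhibitor's target, was not called (camera adjusted p = 0.967). Many of its members were dim, with a median level of log2 5.91 beside the floor of 5.22, which limits what the list test can show. Smad6, Atoh8, Msx2 and Nog lay below the floor and were not tested. Of the list's 10 measured members, Id3 fell, Bambi, a decoy receptor gene, rose by 1.21 ± 0.26, and 8 did not pass, with 1 up and 3 down adjusted over the list alone. Id1, with both dorsomorphin arrays under the floor, was at least 2.45-fold lower and did not pass (adjusted p = 0.0659), and Id2 had a log2 fold of -1.16 ± 0.33 (adjusted p = 0.0700). Among AMPK subunit and fatty acid oxidation genes, Prkag2 fell by 2.93 and Cpt1a, the carnitine palmitoyltransferase gene, by 2.20, while the AMPK-activating kinase gene Stk11 rose by 1.17 log2 units on its brightest probe set. That list had 1 of 16 members up and 3 down, 1 and 4 adjusted over the list alone. It was not called in this comparison (camera adjusted p = 0.985), unlike for dorsomorphin in stimulated cells. Leaving out either control array left 0 genes by limma, with 3004 and 2838 at an unadjusted p under 0.05, and leaving out dorsomorphin replicate 1 or 2 left 1172 or 210. The total of 1825 became 915 after median centring, 883 with only the 4 arrays of this comparison and 3103 with a variance trend and robust fit, and the median log2 fold of all genes moved from -0.24 to -0.01 with median centring.

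The third comparison asked how dorsomorphin changes stimulated T cells. Of the measured list members, 14 of 17 T cell cytokines, 13 of 24 activation-induced transcription factors and 12 of 21 activation and costimulatory surface molecules fell. Il2 fell by 8.02 ± 1.05 log2 units (SE, n = 2 per group, adjusted p = 0.00817) and Ifng by 6.39 ± 0.52 (adjusted p = 0.00576). Egr2 fell by 5.45 ± 0.30 (adjusted p = 0.00491), Myc by 4.89 ± 0.21 (adjusted p = 0.00313) and Spry1, a feedback inhibitor of growth factor signalling, by 5.42 ± 0.25 (adjusted p = 0.00313). Tsc22d3 rose by 4.49 ± 0.85, the Myc antagonist gene Mxd4 by 4.68 ± 1.03 and the chemokine receptor gene Cxcr4 by 4.01 ± 0.73.

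In all, 1358 genes rose and 1738 fell. Every one of the 30 measured ribosome biogenesis genes fell, also when adjusted over the list alone, with Polr1b at -3.74, Rrp12 at -3.56 and Rrp9 at -3.51. The list's camera adjusted p was 3.89e-17, and adjusted p = 0.311 with an estimated correlation. Of 17 T cell cytokines, 14 fell and 3 did not pass, and 15 fell adjusted over the list alone, including Il4 at -6.12 (camera adjusted p = 1.58e-08, and adjusted p = 0.260 with an estimated correlation). Of 24 activation-induced transcription factors, 13 fell, and 15 adjusted over the list alone, with Irf4 at -5.65 and Egr3 at -4.98 (camera adjusted p = 1.57e-06, and adjusted p = 0.311 with an estimated correlation). Of 12 chemokines, 6 fell, and 10 adjusted over the list alone. They included Xcl1 at -6.18 and Ccl4 at -4.53, with a camera adjusted p of 2.95e-05 and adjusted p = 0.260 with an estimated correlation. Surface molecules had 12 of 21 members down and 9 not passed, with 13 adjusted over the list alone (camera adjusted p = 4.80e-06, and adjusted p = 0.311 with an estimated correlation).

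Among metabolic genes, 10 of 22 members of the ATF4 and amino acid response fell and 1 rose, with 11 and 1 adjusted over the list alone. The mitochondrial serine hydroxymethyltransferase gene Shmt2 had a log2 fold of -3.55 and Slc7a5 of -3.30 (camera adjusted p = 0.000442, and adjusted p = 0.390 with an estimated correlation). The hexokinase gene Hk2 fell by 4.42 and Fasn by 2.63 log2 units. Endoplasmic reticulum chaperones had 11 of 19 members down and 1 up, with 13 and 1 adjusted over the list alone, a camera adjusted p of 0.000641 and adjusted p = 0.311 with an estimated correlation. The cell cycle list had 2 of 29 members up and 8 down, with 3 and 8 adjusted over the list alone, and was not called (camera adjusted p = 0.161). Ccnd2 and Cdk4, which drive G1 progression, fell by 3.96 and 3.42, while Cdkn1b, an inhibitor of that step, rose by 3.33 log2 units. Quiescence and homing genes had 6 of 20 members up and 1 down, with 14 and 1 adjusted over the list alone. Foxo1, a transcription factor of resting T cells, rose by 1.71 (camera adjusted p = 0.000417, and adjusted p = 0.518 with an estimated correlation).

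Of 17 CD4 T cell identity genes 6 fell, among them Cd3g at -2.37 and Zap70, a kinase of the receptor, at -2.03, 1 rose and 10 did not pass, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00580, and adjusted p = 0.563 with an estimated correlation). Of 11 regulatory T cell markers 5 fell, and 8 adjusted over the list alone, with Il2ra at -5.14 and Capg at -2.33 (camera adjusted p = 0.000417, and adjusted p = 0.323 with an estimated correlation). Il2ra is also in the list of activation and costimulatory surface molecules. The log2 fold of Foxp3 was -1.08 and did not pass (limma adjusted p = 0.128). Myeloid and dendritic cell markers had 0 of 20 members past the threshold, and 0 adjusted over the list alone, and were not called (camera adjusted p = 0.740). Of 11 B cell markers 3 rose, also 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.161). Of the BMP-SMAD targets, Id1 fell by 2.51 ± 0.51 (adjusted p = 0.0226), Smad7, an inhibitory SMAD, rose by 1.62 ± 0.44 (adjusted p = 0.0488) and Bambi rose by 1.39 ± 0.26. The log2 fold of Id3 was -1.15 ± 0.33 and did not pass (adjusted p = 0.0579), and that of Runx1 was -1.25 ± 0.69 (adjusted p = 0.248). The list as a whole had 2 of 10 members up and 1 down, with 3 and 2 adjusted over the list alone, and was not called (camera adjusted p = 0.320). Receptor and SMAD genes had 5 of 14 members up, and 7 adjusted over the list alone. They included Smad4 at 1.92, with a camera adjusted p of 0.00340 and adjusted p = 0.348 with an estimated correlation. AMPK subunit and fatty acid oxidation genes had 6 of 16 members up and 1 down, also 6 and 1 adjusted over the list alone (camera adjusted p = 0.0269, and adjusted p = 0.495 with an estimated correlation).

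Camera called 18 lists, 3 up and 15 down, and 0 with an estimated correlation. The balance of rises and falls depended on single arrays. The median log2 fold of all genes was 0.01 and 0.18 without stimulated dorsomorphin replicates 1 and 2, and 0.18 and -0.09 without stimulated replicates 1 and 2. Without either control array 1751 genes passed. A limma fit to only the 4 arrays of the comparison called 0 genes, with 4040 at an unadjusted p under 0.05, and median centring gave 684 up and 1531 down, with the median of all genes moving from 0.07 to -0.19.

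**Figure D2:**
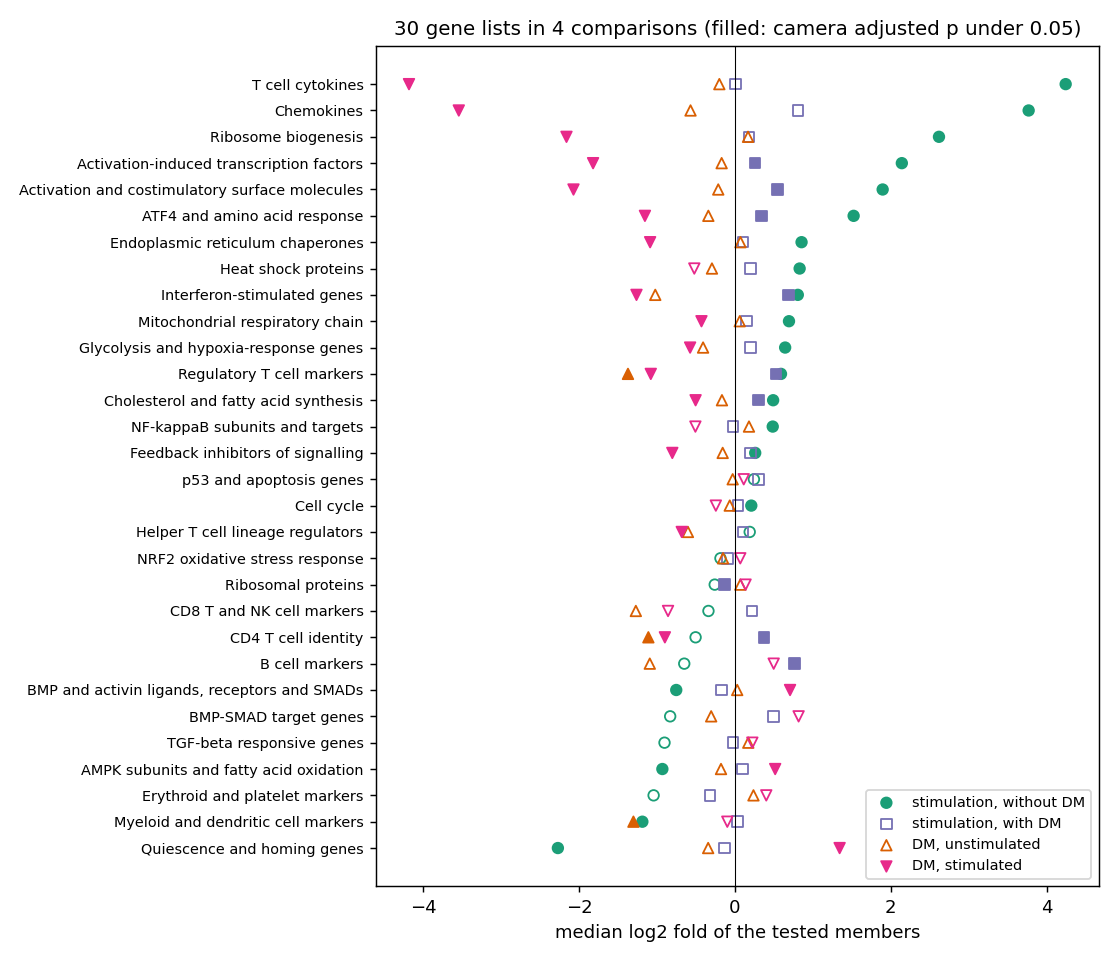
Median log2 fold (horizontal axis) of the measured members of the 30 gene lists (vertical axis) for stimulation without and with dorsomorphin (DM) and for dorsomorphin in unstimulated and stimulated cells. Filled symbols passed camera with its preset correlation, and T cell cytokines lie at 4.24 for stimulation and -4.18 for dorsomorphin in stimulated cells.

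The fourth comparison asked what stimulation does when dorsomorphin is present. No gene passed the limma threshold (0 of 13983), with 539 at an unadjusted p under 0.05 where 699 would be expected by chance. The log2 fold of Il2 was 0.01 ± 1.05 (SE, n = 2 per group), that of Ifng 0.88 ± 0.52, that of Myc 0.25 ± 0.21 and that of Egr1, an immediate early transcription factor, 1.37 ± 0.55. The smallest adjusted p was 0.0897, shared by Galnt9, Metrnl and Actrt3, whose values on the dim side lay under the floor. Genes called up by stimulation without the inhibitor had a median log2 fold of 1.70 there and 0.17 with it, and those called down had -1.71 and -0.03. With dorsomorphin alone, in unstimulated cells, their medians were 0.03 and -0.70. The genes called down were thus also lower with dorsomorphin in cells without stimulation, though both comparisons use the control arrays, which alone favours equal signs. These 3269 genes lay on a slope of 0.06 (r = 0.29 across genes), and all 13983 on one of 0.05 (r = 0.11). The slope was 0.16 without stimulated dorsomorphin replicate 1 and -0.03 without replicate 2 of that group, and 0.0189 and 0.0972 without dorsomorphin replicates 1 and 2.

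By list, camera called 8 up and 1 down in this arm, and 0 with an estimated correlation. Fry called 0 lists here, against 17 for stimulation without dorsomorphin. For dorsomorphin it called 2 in unstimulated and 16 in stimulated cells. The camera calls in this arm were 4 and 0 with median centring, 3 and 0 with no filter on dim genes, and 2 and 0 with the mean of a gene's probe sets. They were 4 and 1 with only the 4 arrays of the comparison, 8 and 0 with cyclic loess, and 9 and 0 with quantile normalization. These counts depended on single arrays: they were 14 and 0 without stimulated dorsomorphin replicate 1, 2 and 2 without its replicate 2, 2 and 1 without dorsomorphin replicate 1, and 1 and 0 without dorsomorphin replicate 2. Cholesterol and fatty acid synthesis genes had a median of 0.30, with 21 of 23 log2 folds above 0 and 0 members past the threshold, also adjusted over the list alone (camera adjusted p = 0.000822, and adjusted p = 0.752 with an estimated correlation). Without dorsomorphin replicate 2 the adjusted p of Cholesterol and fatty acid synthesis was 0.282. Activation-induced transcription factors had a median of 0.26 and 0 members past the threshold, also adjusted over the list alone. Their camera adjusted p was 0.0359, 0.0635 with the replicate block, and adjusted p = 0.752 with an estimated correlation. Activation-induced transcription factors were not called without dorsomorphin replicate 1 or 2 (adjusted p = 0.410 and 0.0701), without stimulated replicate 1 or 2 (0.0663 each), without stimulated dorsomorphin replicate 2 (0.320), with no filter on dim genes (0.0656) or with the mean of a gene's probe sets (0.0966). T cell cytokines had a median of 0.01, with 0 of 17 members past the threshold and 1 higher adjusted over the list alone, and were not called (camera adjusted p = 0.684). Markers of B cells had a median of 0.77, with 0 of 11 members past the threshold and 2 higher adjusted over the list alone (camera adjusted p = 0.00664, and adjusted p = 0.752 with an estimated correlation). With the 60th percentile filter the median of B cell markers was -0.12 and the adjusted p 0.556. The adjusted p was 0.195 without dorsomorphin replicate 1 and 0.150 with the mean of a gene's probe sets. In simulated data with 3000 genes changed in this comparison, limma recovered 72.0% of 4-fold and 19.3% of 2-fold changes. With 200 genes changed by 2- or 4-fold it recovered 0% of either, so a small set of modest changes would not have been detectable here.

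**Figure D3:**
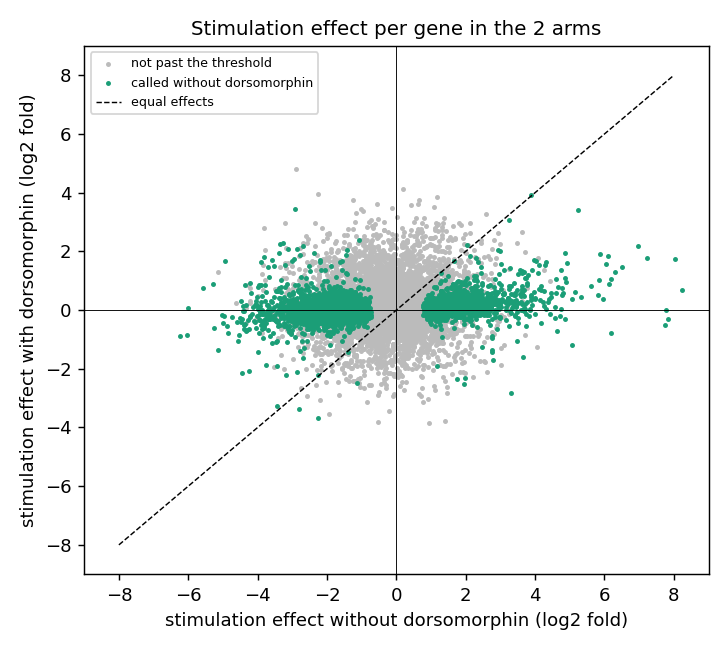
Log2 fold of stimulation without dorsomorphin (horizontal axis) and with it (vertical axis) for 13983 genes, as points. Green points are the 3269 genes called without dorsomorphin, grey points are the others, the dashed line marks equal effects, and the green points lie near 0 on the vertical axis.

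The interaction tested whether dorsomorphin acted differently in stimulated and unstimulated cells, which is also the test of whether stimulation acted differently with and without it. Of 13983 genes, 12 passed, 5 with a higher and 7 with a lower dorsomorphin effect in stimulated cells. The 7 included Spry1 (-5.29 ± 0.35, SE, n = 2 per group, adjusted p = 0.0405), the costimulatory ligand gene Tnfsf14 (-5.28 ± 0.44), Egr2 (-5.14 ± 0.43), the checkpoint ligand gene Pdcd1lg2 (-4.57 ± 0.40) and Myc (-3.26 ± 0.30, adjusted p = 0.0492). Tnfsf14 lay under the floor on all arrays with dorsomorphin, so the size of its difference is not measured on all sides. Il2 had a difference of -7.77 ± 1.49 that did not pass (adjusted p = 0.0678), and Ifng one of -5.26 ± 0.74 (adjusted p = 0.0564). Ribosome biogenesis genes had a median difference of -2.39, with 0 of 30 members past the threshold over all genes and 29 adjusted over the list alone (camera adjusted p = 1.00e-24, and adjusted p = 0.199 with an estimated correlation). T cell cytokines had -3.94, with 0 of 17 members and 13 adjusted over the list alone (camera adjusted p = 2.48e-11, and adjusted p = 0.194 with an estimated correlation). AMPK subunit and fatty acid oxidation genes had 1.05, with 0 of 16 members and 2 higher adjusted over the list alone (camera adjusted p = 0.00897, and adjusted p = 0.406 with an estimated correlation). Markers of other cell types were called in this contrast as well: all 20 myeloid and dendritic cell markers had a difference above 0, with a median of 1.12 and 0 members past the threshold, also adjusted over the list alone (camera adjusted p = 0.00635, and adjusted p = 0.489 with an estimated correlation). Their medians were -1.19 and -1.30 for stimulation and dorsomorphin against control. Between groups other than control they were -0.10 for dorsomorphin in stimulated cells and 0.03 for stimulation with dorsomorphin. The called results for these markers thus all rest on higher signals on the control arrays and are not separate. All 11 B cell markers were above 0, with a median of 1.47, 0 members past the threshold and 2 higher adjusted over the list alone (camera adjusted p = 0.00978, and adjusted p = 0.369 with an estimated correlation). With the 60th percentile filter the adjusted p of B cell markers was 0.118. The 12 genes became 0 with the replicate number, by which the Dap and Thr spike-in controls split, as a block, with median centring and with any one array left out except stimulated replicate 1, without which 803 passed. At an unadjusted p under 0.05 there were 3687 genes, and a variance trend with a robust fit called 2036, 1298 higher and 738 lower. Higher calls also outnumbered lower ones with the 60th percentile filter (1231 and 636) and with log2 of the value plus 32 (1002 and 543). Quantile normalization gave 208 and 199, and cyclic loess 18 and 29, so the direction of the split depended on the processing. The median difference over all genes was 0.35, and -0.14 with median centring.

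The 2 dorsomorphin comparisons, which share no arrays, had 138 rising genes in common where independent lists would share 26.0, and 630 falling genes where they would share 194. Only 5 genes rose in unstimulated and fell in stimulated cells (33.3 for independent lists), and 41 did the reverse (151). Both comparisons take each gene's spread from the same fit, which alone makes shared calls more frequent than in independent lists. The shared falls included Cd3g, Cd5, Capg, Ccnd2 and Myc. Across the 4107 genes called in either state the effect in stimulated cells had a slope of 0.60 on that in unstimulated cells (r = 0.45 across genes), a selection that favours large effects, and across all 13983 genes it was 0.39 (r = 0.34). Of the genes raised by stimulation, 865 fell with dorsomorphin in stimulated cells (156 for independent lists), and of those lowered, 863 rose (195). Both of these comparisons use the stimulated arrays, which alone makes opposite signs more frequent. Over all genes, 72.2% had opposite signs, against 66.6% in 100 simulated data sets with no effect. In a split made after seeing the data, the stimulation effect came from 1 stimulated array and the dorsomorphin effect from the other, so that no array was shared and the simulated share does not apply, a lone array being assumed to vary like the other groups. Both effects still took each gene's spread from the same remaining arrays, so the counts for independent lists are a low baseline here too. With stimulation from replicate 1, 227 genes rose and then fell (23.3 for independent lists) and 250 fell and then rose (42.0), and 66.6% of all genes had opposite signs. With stimulation from replicate 2 these were 353 (47.9), 289 (64.01) and 63.2%. Both overlap counts were 0 without either control array and 0 for the fits to 4 arrays. The 768 genes moved alike by dorsomorphin in both states became 481 and 130 without dorsomorphin replicates 1 and 2, and 463 and 339 without stimulated replicates 1 and 2. They became 298 and 367 without stimulated dorsomorphin replicates 1 and 2. The 1728 genes moved in opposite directions became 403 without stimulated replicate 2 and 622 without stimulated dorsomorphin replicate 1.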

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

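The tests of between-array scaling and of replicate 2 alone, with their limits, were chosen only after the result was seen. The test on 385 genes was fixed before its own result, but after related values of replicate 1 had been seen. The difference of the dorsomorphin effect between stimulated and unstimulated cells marked 12 genes and 18 lists for a closer look, by the interaction test. With an estimated correlation 0 of these lists were called, and with the replicate number as a block 0 genes passed, with 4477 at an unadjusted p under 0.05 by limma. The list medians (log2) were -2.39 for ribosome biogenesis (29 of 30 members lower adjusted over the list alone, and adjusted p = 0.199 with an estimated correlation) and -3.94 for T cell cytokines (13 of 17, and adjusted p = 0.194 with an estimated correlation). For activation-induced transcription factors it was -1.97 (2 of 24 lower over all genes and 7 adjusted over the list alone, and adjusted p = 0.194 with an estimated correlation). The single genes were Galnt9 (6.37), Apobec1 (5.61), Ift172 (4.63), Ripor1 (3.52), Spry1 (-5.29), Tnfsf14 (-5.28), Egr2 (-5.14), Pdcd1lg2 (-4.57), Slc35d3 (-3.62), Ccdc86 (-3.61) and Myc (-3.26), each in log2 units. Galnt9, Apobec1, Ift172, Tnfsf14 and Slc35d3 had group means under the floor in at least 1 group, so the size of their differences is not measured on all sides.

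The pattern behind most of these differences is that no gene passed for stimulation once dorsomorphin was present, and that the array of stimulated dorsomorphin replicate 1 lay closer to dorsomorphin replicate 1 (SD of the log2 difference 0.836) than any 2 arrays of 1 group lay to each other (0.854 to 1.01), while replicate 2 of that group lay at 0.992 from dorsomorphin replicate 2 and at 1.00 from its own replicate. The slope of the stimulation effect with on without dorsomorphin was at most 0.0652 over cyclic loess and quantile normalization (0.0662 with median centring, which acts on it only through the genes called). A rescaling of arrays can hardly change a slope across genes, so the slope cannot decide on between-array scaling. With each of these scalings 0 genes passed for stimulation with dorsomorphin. Unstimulated RNA on that array as the whole cause is opposed by replicate 2 alone, where 2079 genes picked in replicate 1 kept 22.7% of their rise. The median log2 difference of those genes with dorsomorphin was 0.33, against 0.08 for all genes. On that array 2275 genes picked in replicate 2 kept 2.13%, with a median of 0.025 against 0.023 for all genes. There, 385 genes that rose in replicate 2 in both arms had a median difference of 0.195 (upper limit of 10000 random lists matched on mean level 0.104). That limit treats genes as independent, while genes picked for rising together may also move together between any 2 arrays. The value therefore cannot decide between wholly unstimulated RNA, a mixture and weaker stimulation, which all stay open. A hypothesis that also stays open is that dorsomorphin may block most of the transcriptional response to stimulation, on which the interaction test of 12 genes bears, and which of its targets would be involved was not tested.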

How the results depend on the processing

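Quantile normalization and log2 of the value plus 32 were chosen after seeing the data. The cause of the changes below was not tested, except that a stricter threshold leaves less to call. Fewer arrays never raised a count of genes, apart from that of the interaction without stimulated replicate 1. For stimulation without dorsomorphin the 3269 genes became 1668 with only the 4 arrays of the comparison, 2122 with no dim filter, 2063 with median centring and 316 at an adjusted p under 0.01, and 0 to 2940 with 1 array left out. For dorsomorphin in unstimulated cells the 1825 became 883, 927, 915 and 48 in the same order, 2968 with the 60th percentile filter, 3103 with trend and robust variance, 1058 with the mean of a gene's probe sets and 2881 with log2 of the value plus 32, and 0 to 1591 with 1 array left out. For dorsomorphin in stimulated cells the 3096 became 0 with only 4 arrays and 734 at 0.01, and 1000 to 2648 with 1 array left out. For stimulation with dorsomorphin the 0 became 2 with the 60th percentile filter, and 0 to 0 with 1 array left out. The 12 interaction genes became 0 with the replicate block, with no filter, with median centring and at 0.01, then 1867 with the 60th percentile filter, 47 with cyclic loess, 2036 with trend and robust variance, 3 with the mean of probe sets, 407 with quantile normalization and 1545 with log2 of the value plus 32, and 0 to 803 with 1 array left out; limma found 4477 at an unadjusted p under 0.05 with the block. The interaction had no fit to 4 arrays. The 768 genes shared by both dorsomorphin comparisons became 0 with only 4 arrays, 336 with no filter, 1373 with the 60th percentile filter, 409 with median centring, 1366 with trend and robust variance, 442 with the mean of probe sets, 25 at 0.01 and 1160 with log2 of the value plus 32, and 0 to 481 with 1 array left out. The 1728 genes moved one way by stimulation and the other by dorsomorphin became 0 with only 4 arrays, 1047 with no filter, 1072 with median centring and 200 at 0.01, and 0 to 1700 with 1 array left out. The slope of 0.06 ranged from -0.0255 to 0.165 with 1 array left out, and had no value without a control array, where no gene was called. The 50 list calls of the 4 comparisons became 0 with an estimated correlation and 41 to 51 with 1 array left out, and the 18 of the interaction became 0, 10 with fry, and 15 to 19. Deviations from group means correlated at 0.07 to 0.18 between arrays with the same number, over 0.1 in 4 of 6 pairs of groups, and the third principal component (9.58% of the variance) separated the numbers, at 6.99 to 41.8 and -40.9 to -18.4. These values, with the split of the Dap and Thr spike-ins, point to an effect shared by the arrays of a number, which the main fit leaves out. The labels do not say what a number marks. Because not every correlation was over 0.1, the number was kept as an alternative block. With the replicate block, beyond the interaction, the counts of genes stayed within 1.5 times their values, and of 360 named results 337 kept their call, 21 lost it and 2 gained it. Where 1 array of a group was left out, the lone array was assumed to vary like the other groups. Named results called in the main fit or in the other setting reversed sign only with the mean of probe sets: Sel1l with dorsomorphin in unstimulated cells to 0.10, and in stimulated cells Stk11 to -0.23 and Ndufb8 to 0.0586. Over all settings, 26 more sign changes were of named results called in neither. Signals near the floor limit the rises with dorsomorphin in unstimulated cells most.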

Other observations

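The tests of the share of rising genes and of the spike-ins, with their limits, were chosen only after the results were seen. Heat shock proteins had 6 of 14 members up and 1 down with stimulation alone, among them the mitochondrial chaperone genes Hspd1 at 3.07 and Hspe1 at 1.84, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.00720, and adjusted p = 0.480 with an estimated correlation). Endoplasmic reticulum chaperones had 10 of 19 up, and 13 adjusted over the list alone, with Sdf2l1 at 2.65 and Hspa5 at 1.91 (camera adjusted p = 6.85e-06, and adjusted p = 0.176 with an estimated correlation). Of 24 respiratory chain genes 4 rose, with Cycs at 1.72, and 8 adjusted over the list alone (camera adjusted p = 1.70e-06, and adjusted p = 0.441 with an estimated correlation). Of 17 ribosomal protein genes 0 passed in any comparison, and 0 adjusted over the list alone, with medians of -0.26 for stimulation and 0.07 for dorsomorphin in unstimulated cells. Camera called that list for stimulation with dorsomorphin, at a median of -0.14 (adjusted p = 0.0268, and adjusted p = 0.763 with an estimated correlation). That call on Ribosomal proteins ended with median centring (adjusted p = 0.0648), cyclic loess (0.153) and quantile normalization (0.840, median -0.00397), with no filter on dim genes (0.0656), the mean of a gene's probe sets (0.145) or only the 4 arrays (0.0638), and without dorsomorphin replicate 2 (0.768) or stimulated dorsomorphin replicate 1 (0.621). Gzmb, a cytotoxic granule protease gene, rose by 4.78 with stimulation and fell by 4.23 log2 units with dorsomorphin in stimulated cells.

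More genes fell than rose with dorsomorphin in unstimulated cells, with 14.7% of the 1825 called genes rising. Between-array scaling as the cause is opposed by the share of rising genes under other scalings, of which the highest over median centring, cyclic loess and quantile normalization was 21.2%. Noise of dim genes is opposed by a share of 19.7% with the 60th percentile filter. An effect of dorsomorphin itself stays open as an untested hypothesis.

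Poly-A spike-ins were lower on the stimulated arrays without dorsomorphin, at a mean log2 signal of 9.31 and 10.01 against 10.38 to 10.90 on the other 6 arrays, and hybridization controls were lower there too, at 11.77 and 12.06 against 12.16 to 12.67. Array scaling and brightness would lower both alike, but poly-A minus hybridization signal was lowest on the stimulated array within each replicate number, at -1.76 against -1.57 to -1.36 and at -2.75 against -2.23 to -1.76. Stimulated minus the other arrays of the number was -0.511 (95% interval -0.96 to -0.06), but stimulated minus control in a fit with all 4 groups was -0.462 (-0.397 and -0.527 in replicates 1 and 2, 95% interval -1.30 to 0.38), while dorsomorphin minus control was -0.21 and 0.46, with opposite signs. The direction thus goes against scaling and brightness as the whole cause, but with 2 stimulated arrays the interval against control included 0, which leaves them open. A higher mRNA share of the total RNA in stimulated cells, a hypothesis, stays open as well, since the amounts of spike-in added are not given in the sources used here.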
